A study of Homo sapiens with 20 samples.

How the data were processed

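RNA was measured in SUM44, an established human breast cancer cell line derived from invasive lobular carcinoma. Per the labels, cells were hormone deprived for 3 days in medium with charcoal-stripped serum and were then given 1 nM estradiol (E2) or its ethanol vehicle for 3 h or 24 h. A group taken at 0 h, before any addition, served as the baseline. The series text gives the serum as 2% and the sample text as 10%, which was not settled here. There were 20 Affymetrix human expression arrays in 5 groups of 4, and the series text calls the replicates biological quadruplicates. Groups and replicate letters were taken from the sample titles. The treatment field of the 4 arrays titled E2 at 24 h reads baseline, while their titles and descriptions name E2, and they were grouped by title.

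The deposited values are log2 expression per probe set, made by the authors with RMA and the affy package per the submitters' processing notes. RMA corrects background, normalizes across arrays and summarises the probes of a probe set. Versions and parameters of that step were not given in the sources used here. Quantile normalization of this kind forces similar distributions on all arrays, so a change of total RNA per cell would not appear in these values. The number of arrays limits the precision.

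The table held 22277 probe sets, of which 62 were control probe sets and were left out. The platform annotation gave 1 gene symbol for 19064 probe sets, several for 1043 and none for 2108 that stay unnamed here. The Entrez numbers of 19052 of the single-symbol probe sets matched the RefSeq gene table, which changed 0 symbols. For each gene the probe set with the highest mean over the 20 arrays was used, giving 11963 genes, 4310 of which had more than 1 probe set. No filter on dim probe sets was applied. A gene is called dim in a comparison where the means of both groups lie below a log2 level of 6.11, under which the lowest 25% of genes lie. Where the mean of 1 group alone lies below that level, the text says so. Detection calls were not used here, and signals near background compress a change, so the size of such a change is less certain.

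Values were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with all 20 arrays in 1 fit, a mean per group and no block. Adjusted p-values are Benjamini-Hochberg values over all genes tested in a comparison, with a threshold of 0.05. The comparisons were E2 against vehicle at each time, the difference between those effects, and vehicle at each time against baseline. Errors given after ± are standard errors of the limma fit unless SD is named. Gene lists of 21 kinds were tested with limma's camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison, and again with an estimated correlation and with fry. Lists with fewer than 5 measured members were not to be tested. The lists covered estrogen-induced and estrogen-repressed genes of ductal lines, luminal identity, receptor coregulators, immediate-early genes, G1/S, G2/M, quiescence, ribosome biogenesis, cholesterol, fatty acids, amino acid and unfolded protein responses, WNT, receptor tyrosine kinases, adhesion, the BCL2 family, interferon, hypoxia, and basal, stromal and immune or endothelial markers.

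The design, the lists, the alternatives and the rule for naming genes were fixed before the data were examined, except the lists and alternatives said below to be chosen afterwards. For each E2 comparison the rule takes the 10 largest increases and 10 largest decreases among genes past the threshold whose 4 E2 arrays all lay on 1 side of their 4 vehicle arrays. It adds up to 3 members of each list by smallest p, with members used as examples of those that did not pass also taken by smallest p, and always ESR1, PGR, GREB1, TFF1, CDH1, WNT4 and FGFR1. For the difference between times it takes the 6 largest in each direction, and for each vehicle comparison the 5 largest in each direction under the same condition. Genes named outside this rule are said to be so. Genes whose probe set name marks possible cross-hybridisation are named with that caveat.

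The fit was tested on simulated data for E2 against vehicle at 3 h over 11963 genes. It recovered 88% of genes changed 1.25-fold and 100% of those changed 1.5-fold, 2-fold or 4-fold, 50 genes each. Of the 204 genes it called, 10 were unchanged. In a second simulation, for E2 at 24 h, the G2/M list among the 21 was shifted. Camera called 0 of the lists that share no gene with it. Genes were drawn independently there, so lists of correlated genes were not covered. Alternatives covered the arrays in the fit, a replicate block, normalization, dim genes, probe set choice, the variance prior, array weights, thresholds, the reference group, single arrays left out and the list test. No columns of other samples were used. The value of 1 of the 3 control transcripts examined for RNA quality is not reported here.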

Results

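Genome-wide transcript levels of SUM44 cells were compared between estradiol and vehicle after 3 h and 24 h, with an untreated baseline at 0 h. SUM44 is an estrogen receptor-positive line of invasive lobular carcinoma, and the series title names the estrogen-mediated gene expression of this tumour type as its subject. Each of the 5 groups held 4 arrays. Correlations between arrays ran from 0.998 to 0.999 within groups and from 0.988 to 0.998 between groups, and 0 pairs of arrays were identical. The first principal component held 47.0% of the variance and the second 25.3%. The number of arrays limits the precision of every value.

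**Figure D1:**
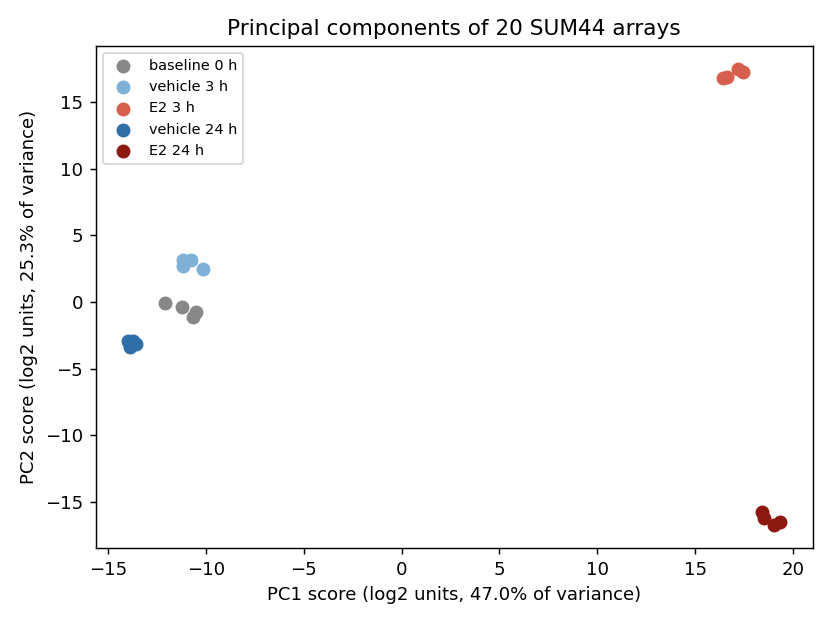
Scores of the 20 arrays on the first and second principal components, in log2 units, with 1 point per array coloured by group. The first component (47.0% of variance) parts both E2 groups from vehicle and baseline, and the second (25.3%) parts E2 at 3 h from E2 at 24 h.

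Estradiol raised RASGRP1, HSD11B2 and EGR3 and lowered DLX2, RND3 and GATA3 within 3 h. RASGRP1, an exchange factor that activates Ras, rose by 4.18 ± 0.09 on the log2 scale, from 6.58 ± 0.10 to 10.76 ± 0.10 (SD, n = 4), which is 18.1-fold. HSD11B2, which inactivates cortisol, rose by 3.52 ± 0.11, and the transcription factor EGR3 rose by 3.32 ± 0.13. The homeobox gene DLX2 fell by 3.38 ± 0.07 and RND3 fell by 2.84 ± 0.07. GATA3, a transcription factor of luminal identity, fell by 2.07 ± 0.04, which is 4.19-fold, and all 3 of its probe sets were called in that direction.

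The other large increases at 3 h were in KAZN (2.60 ± 0.05), GADD45B (2.55 ± 0.05), SMAD7, an inhibitor of TGF-beta signalling (2.52 ± 0.05), SPRY4, an inhibitor of receptor tyrosine kinase signalling (2.37 ± 0.06), MYC (2.35 ± 0.09) and MICB (2.34 ± 0.05). GDF15 rose by 2.44 ± 0.10 on a probe set that may cross-hybridise, and only 1 of its 2 probe sets was called. Decreases followed in RGS2, a regulator of G protein signalling (-2.82 ± 0.07), NAV3 (-2.32 ± 0.06), RASL11B (-2.26 ± 0.05), the cyclic AMP phosphodiesterase PDE4B (-2.22 ± 0.07), ARSJ (-2.17 ± 0.09), PPFIBP2 (-2.16 ± 0.05) and PPP1R3C (-2.04 ± 0.04). Where a gene had several probe sets, not all were called for DLX2 (1 of 2), KAZN (2 of 3), NAV3 (1 of 3) and PDE4B (2 of 3), and 0 were called in the opposite direction. Means below the level taken as dim were those of HSD11B2 and EGR3 in vehicle and of DLX2, RASL11B and PDE4B with E2. For ARSJ and DLX2 the vehicle arrays at 3 h all lay above the baseline arrays, so part of their decrease is a rise in vehicle. Their E2 arrays all lay below the baseline arrays. Among these 20 genes the limma fit gave Benjamini-Hochberg adjusted p-values from 1.7e-18 for GATA3 to 1e-13 for GDF15.

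Genes known to be induced by estrogen in ductal breast cancer lines mostly rose at 3 h. Of 37 measured, 30 rose and 1 fell, the same counts as when adjusted over the list alone, and the median change was 0.77. RET, a receptor tyrosine kinase, rose by 2.21 ± 0.03, the small heat shock protein gene HSPB8 by 1.72 ± 0.04 and the ubiquitin ligase gene SIAH2 by 1.82 ± 0.05. GREB1 rose by 1.70 ± 0.07. PGR, the progesterone receptor, rose by 1.01 ± 0.14 on a dim probe set (5.17 ± 0.22 with E2, SD, n = 4). TFF1, already at 13.51 ± 0.01 (SD, n = 4) in vehicle, rose by 0.12 ± 0.02. Camera gave this list a Benjamini-Hochberg adjusted p of 4.5e-25 on limma's log2 fit, and adjusted p = 4.9e-05 with an estimated correlation.

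Of 17 measured genes known to be repressed by estrogen in ductal lines, 9 fell and 2 rose (9 and 3 adjusted over the list alone), with a median of -0.15. The ephrin gene EFNA1 fell by 1.17 ± 0.03, the pro-apoptotic gene BIK by 1.12 ± 0.04 and CCNG2 by 0.75 ± 0.03. Camera gave a Benjamini-Hochberg adjusted p of 0.0091 and adjusted p = 0.1 with an estimated correlation. Immediate-early genes went both ways, 10 of 23 rising and 6 falling (11 and 6 adjusted over the list alone), with FOSL2 up by 1.93 ± 0.05 beside EGR3 and MYC. Camera called that list higher at a Benjamini-Hochberg adjusted p of 0.0075, with adjusted p = 0.16 with an estimated correlation. Of 21 adhesion and mesenchymal genes, 10 fell and 2 rose (also 10 and 2 adjusted over the list alone). They included the mesenchymal transcription factor TWIST1 (-1.78 ± 0.04) and the tight junction genes OCLN (-0.92 ± 0.04) and CLDN4 (-0.78 ± 0.04), so members of both kinds fell. That list had a Benjamini-Hochberg adjusted p of 0.011 by camera, and adjusted p = 0.064 with an estimated correlation.

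CDH1, the adhesion gene whose loss marks lobular carcinoma, rose by 0.75 ± 0.05 at 3 h. WNT4 rose by 1.65 ± 0.06 and the WNT receptor gene FZD7 by 1.98 ± 0.04, while 4 of 28 WNT genes rose and 9 fell and the list was not called. ESR1, the estrogen receptor, fell by 0.29 ± 0.03, with 8 of 9 probe sets called, and FGFR1 by 0.31 ± 0.04. In the hypoxia and glycolysis list, also not called, 5 of 19 rose and 3 fell, with PFKFB3 up by 1.88 ± 0.05, VEGFA by 1.15 ± 0.04 and the glucose transporter gene SLC2A1 by 1.08 ± 0.04. Luminal identity genes split into 6 higher and 6 lower of 17. Of 13 stromal markers 1 rose and 0 fell, and of 14 immune and endothelial markers 1 rose and 1 fell.

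In all, 3720 of 11963 genes (31.1%) passed at 3 h by limma at the Benjamini-Hochberg threshold, 1619 higher and 2101 lower. With each array centred on its median the split was 1935 higher and 1907 lower, so the excess of lower genes depends on the scaling. At least a 1.5-fold change was seen for 326 of the higher and 309 of the lower genes, and the median size among called genes was 0.26. The 4 E2 arrays lay wholly above or below the 4 vehicle arrays for 3660 genes (30.6%), against 2.86% by chance. Camera called 4 of 21 lists, of which 1 was called with an estimated correlation. The log2 difference between the 3' and 5' control probe sets, which accompanies these lists, was 0.385 ± 0.032 with E2 and 0.315 ± 0.027 with vehicle for ACTB (SD, n = 4). For GAPDH it was -0.138 ± 0.011 with E2 and -0.116 ± 0.0085 with vehicle (SD, n = 4), and the arrays of the groups did not overlap for either transcript. At least as many lists were called in 3 of the 35 splits of these 8 arrays, the real one counted.

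**Figure D2:**
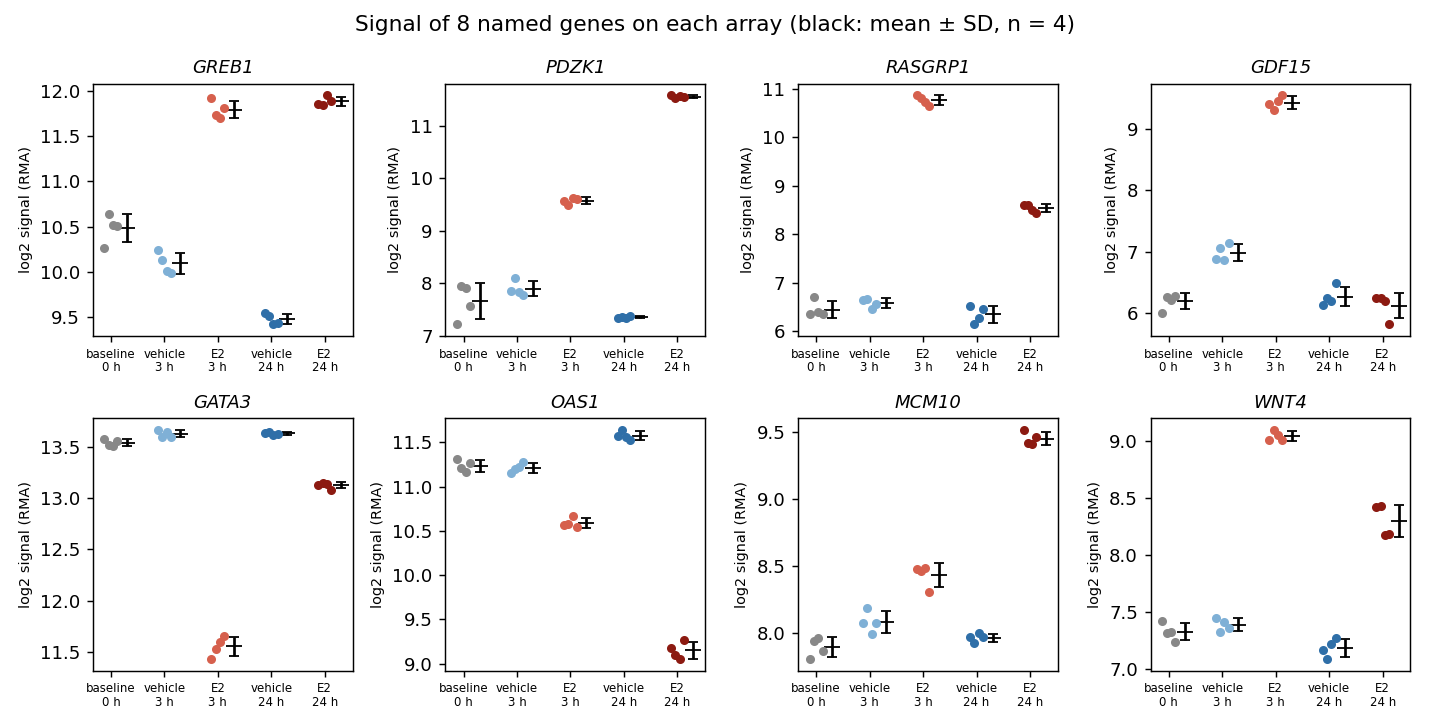
Log2 signal of 8 genes on each of the 20 arrays by group, 1 coloured point per array, with black marks for the mean and SD (n = 4). RASGRP1 reaches 10.76 with E2 at 3 h against 6.58 in vehicle, and PDZK1 reaches 11.56 with E2 at 24 h against 7.35. Axes do not start at 0.

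At 24 h PDZK1, which encodes a scaffold protein, rose by 4.21 ± 0.11, from 7.35 ± 0.02 to 11.56 ± 0.03 (SD, n = 4), an 18.5-fold change. S100A7 rose by 4.15 ± 0.08, which is 17.8-fold. The metalloproteinase gene MMP26 rose by 4.15 ± 0.10 from a dim mean of 5.21 in vehicle, so no fold is given. The helicase subunit gene MCM6 rose by 1.01 ± 0.03. OAS1, an interferon-induced gene, fell by 2.43 ± 0.05, which is 5.39-fold.

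Further increases at 24 h were in EGFL6 (3.27 ± 0.10), EGR3 (3.16 ± 0.13), DHRS2 (2.70 ± 0.06), DOCK10 (2.67 ± 0.11), ATRNL1 (2.49 ± 0.08), the peroxisomal oxidase gene ACOX2 (2.48 ± 0.06) and GREB1 (2.41 ± 0.07). The largest decreases were in SERHL2, on a probe set that may cross-hybridise (-3.10 ± 0.04), the calcium channel subunit gene CACNA2D3 (-2.90 ± 0.06) and the cannabinoid receptor gene CNR1 (-2.82 ± 0.10, with 1 of 3 probe sets called). Next came ATP8A2 (-2.70 ± 0.06), STON1 (-2.57 ± 0.10), the histidine decarboxylase gene HDC (-2.55 ± 0.04) and BAMBI, a decoy receptor of TGF-beta signalling (-2.53 ± 0.07). The chemokine receptor gene CX3CR1 (-2.44 ± 0.10) and the urea transporter gene SLC14A1, which is dim (-2.34 ± 0.14), completed the set. The means of EGR3 and DOCK10 in vehicle and of CACNA2D3, CNR1 and CX3CR1 with E2 were also below the level taken as dim. For ATRNL1, GREB1, DHRS2 and ACOX2 the vehicle arrays at 24 h all lay below the baseline arrays, so part of their increase is a fall in vehicle. For HDC, ATP8A2, CNR1 and BAMBI they all lay above the baseline arrays, so part of their decrease is a rise in vehicle. Among these 20 genes limma's Benjamini-Hochberg adjusted p-values ran from 1.2e-19 for SERHL2 to 2.9e-11 for SLC14A1.

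Of 42 measured G1/S and DNA replication genes, 40 rose and 1 fell at 24 h, the same as when adjusted over the list alone, with a median of 0.77. MCM10 rose by 1.49 ± 0.05 and MCM5 by 1.15 ± 0.05. Camera gave a Benjamini-Hochberg adjusted p of 1.2e-23 and adjusted p = 0.026 with an estimated correlation. Of 40 G2/M and mitosis genes, 33 rose and 2 fell (34 and 3 adjusted over the list alone), by a median of 0.23. PRC1 rose by 0.64 ± 0.04, CDK1 by 0.56 ± 0.04 and CKS1B by 0.45 ± 0.03. That list had a Benjamini-Hochberg adjusted p of 2e-08 by camera, and adjusted p = 0.17 with an estimated correlation. Cholesterol synthesis and uptake genes also rose, 14 of 18 against 2 that fell (14 and 2 adjusted over the list alone), by a median of 0.40. ACAT2 rose by 0.89 ± 0.03, EBP by 0.67 ± 0.03 and IDI1, on a probe set that may cross-hybridise, by 0.63 ± 0.03. Camera's Benjamini-Hochberg adjusted p was 4.9e-07, with adjusted p = 0.046 with an estimated correlation. The median of the cholesterol genes in vehicle at 24 h was -0.13 against baseline, so part of their rise is a fall in vehicle.

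Estrogen-induced genes of ductal lines rose in 28 of 37 cases at 24 h and fell in 7, also 28 and 7 adjusted over the list alone, with a median of 0.72. RET rose by 1.74 ± 0.03, the fatty acid elongase gene ELOVL2 by 1.61 ± 0.04 and HSPB8 by 1.57 ± 0.04. PGR rose by 0.72 ± 0.14 on its dim probe set and TFF1 by 0.14 ± 0.02. Camera gave a Benjamini-Hochberg adjusted p of 1.7e-10 and adjusted p = 0.0064 with an estimated correlation. Estrogen-repressed genes fell in 9 of 17 cases and rose in 2 (10 and 3 adjusted over the list alone), with BCAS1 down by 1.48 ± 0.03 among them. EFNA1 fell by 1.34 ± 0.03 and NDRG1 fell by 1.13 ± 0.03, and camera's Benjamini-Hochberg adjusted p was 0.00042, with adjusted p = 0.031 with an estimated correlation.

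At this time WNT4 rose by 1.11 ± 0.06 and CDH1 by 0.17 ± 0.05, with 1 of 2 CDH1 probe sets called. ESR1 fell by 0.18 ± 0.03 (6 of 9 probe sets called) and FGFR1 by 0.44 ± 0.04 (5 of 6). Interferon response genes, a list that was not called, fell in 10 of 24 cases and rose in 4. Of the stromal markers 3 of 13 rose and 2 fell, of the immune and endothelial markers 3 of 14 rose and 1 fell, and of the basal markers 4 of 8 rose and 0 fell.

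At 24 h limma called 5469 genes (45.7%) at the Benjamini-Hochberg threshold, 2572 higher and 2897 lower, of which 361 and 398 changed at least 1.5-fold. The split was 2746 higher and 2766 lower with each array centred on its median, and 2785 and 2624 with each array's level trend removed, an alternative chosen after seeing the data, so its direction depends on the scaling. The median size among called genes was 0.24, and 4949 genes (41.4%) showed no overlap between E2 and vehicle arrays, against 2.86% by chance. Camera called 5 of 21 lists and 4 with an estimated correlation. In 6 of the 35 splits of these 8 arrays, the real one counted, at least as many lists were called.

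**Figure D3:**
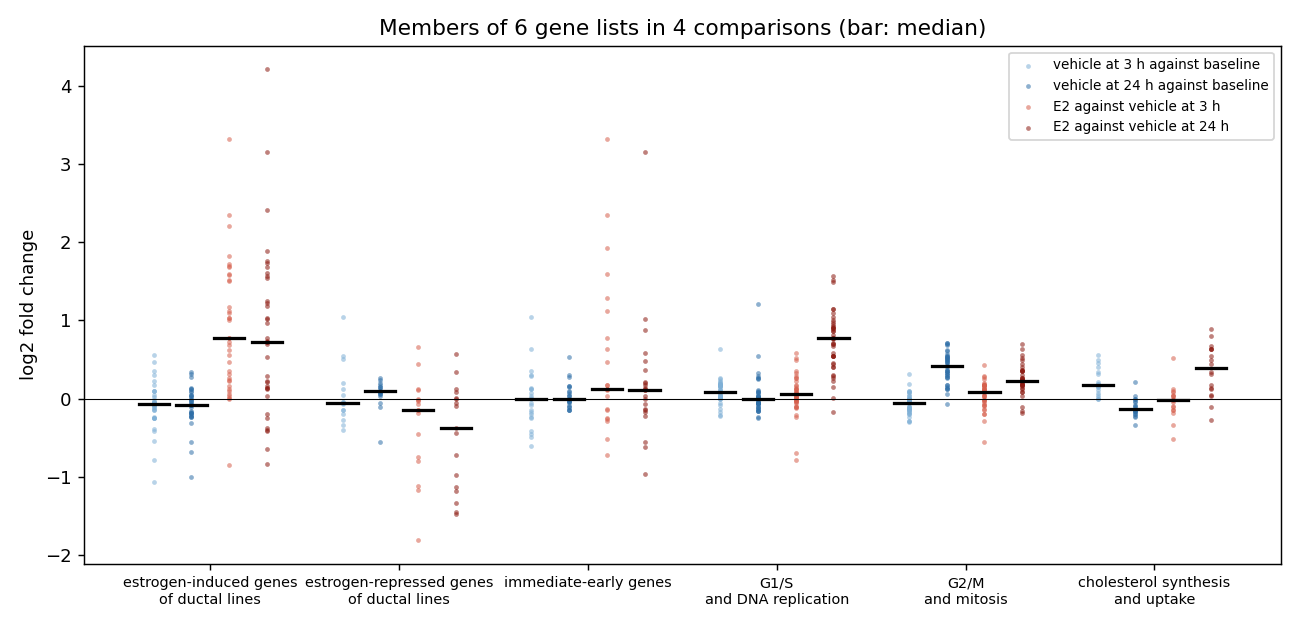
Log2 fold changes of the measured members of 6 gene lists in 4 comparisons, 1 point per gene, with a black bar at the median. The G1/S median lies at 0.77 for E2 at 24 h against 0.05 at 3 h, and the G2/M median at 0.42 for vehicle at 24 h.

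The effects at the 2 times overlapped in part. Called in both and higher in both were 846 genes, where independent lists of those sizes would share 348.1, and 1223 were lower in both against 508.8. Opposite directions were seen for 263 genes that were higher at 3 h and lower at 24 h (392.1 for independent lists) and 249 the other way (451.7). With at least a 1.5-fold change at both times, 139 genes were higher in both (9.84 for independent lists), 109 lower in both (10.3), and 3 and 4 changed direction. Across genes, which are not independent replicates, the log2 fold changes had a Pearson r of 0.488 and a Spearman correlation of 0.373. The compared vehicle arrays differ between the times, so no control array is shared.

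**Figure D4:**
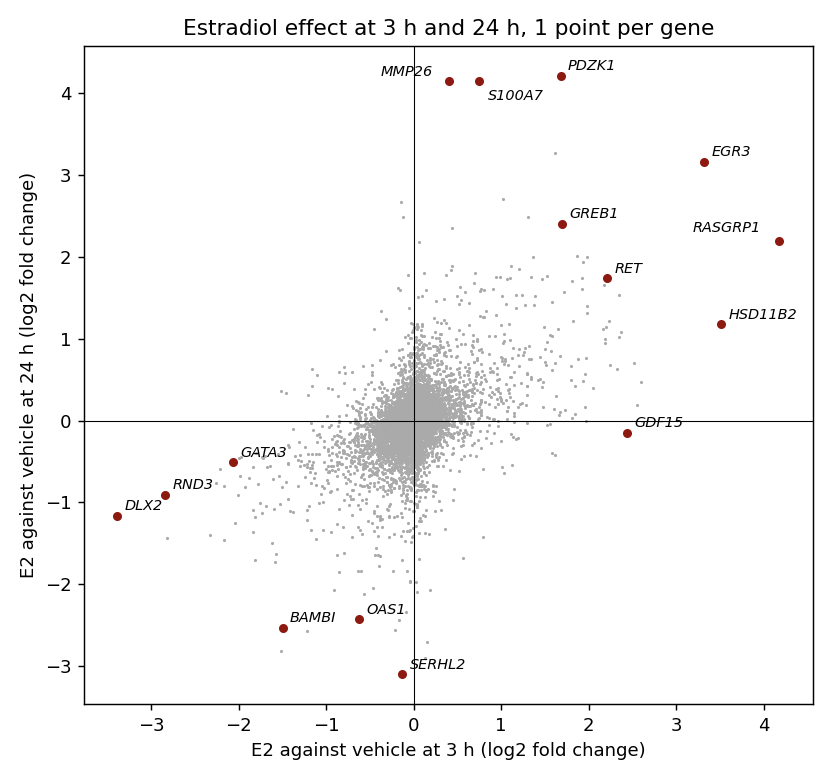
Log2 fold change of E2 against vehicle at 3 h (horizontal) and 24 h (vertical), 1 point per gene for 11963 genes, with 15 named genes in red. EGR3 lies at 3.32 and 3.16, whereas GDF15 lies at 2.44 and -0.15.

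The test of the difference between the effects asked which responses were early and which late. Each effect is taken against vehicle of its own time, so movement of vehicle between 3 h and 24 h also enters the difference. The ATRNL1 vehicle arrays, for example, lay lower at 24 h than at 3 h. MMP26 had the largest positive difference, 3.74 ± 0.15 (24 h minus 3 h), followed by S100A7 (3.40 ± 0.11), DOCK10 (2.81 ± 0.15), ATRNL1 (2.61 ± 0.12) and PDZK1 (2.53 ± 0.16). MMP26 and DOCK10 were dim in both groups at 3 h. DLX2, at 2.22 ± 0.10, was lowered less at 24 h than at 3 h. The largest negative differences were in CACNA2D3 (-3.03 ± 0.09), SERHL2 (-2.97 ± 0.06), ATP8A2 (-2.86 ± 0.08) and HDC (-2.34 ± 0.06), which were lower at 24 h. GDF15 (-2.59 ± 0.14) and GADD45B (-2.36 ± 0.07) had risen at 3 h. GDF15 at 24 h stood at -0.15 ± 0.10 with a limma Benjamini-Hochberg adjusted p of 0.24.

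Of the G1/S genes 37 of 42 had a positive difference (24 h minus 3 h) and 0 a negative (39 and 0 adjusted over the list alone), and camera's Benjamini-Hochberg adjusted p was 4.8e-24, with adjusted p = 0.046 with an estimated correlation. For the cholesterol genes 15 of 18 differences were positive and 1 negative, in the same counts when adjusted over the list alone (Benjamini-Hochberg adjusted p = 2.7e-08 by camera on limma's fit, and adjusted p = 0.046 with an estimated correlation). Against baseline the cholesterol median was 0.17 in vehicle at 3 h and -0.13 in vehicle at 24 h, so part of this difference is movement of vehicle. G2/M genes had positive differences in 26 of 40 cases and negative in 3 (27 and 3 adjusted over the list alone), with adjusted p = 0.3 with an estimated correlation. Camera also called the differences of luminal identity genes positive, 8 of 17 against 1 negative, among them GATA3, which was lowered less at 24 h (adjusted p = 0.084 with an estimated correlation). It called those of BCL2 family genes negative, 8 of 14 against 0 positive, among them BIK (adjusted p = 0.22 with an estimated correlation). The decrease of BIK against its own vehicle was larger at 24 h, but its E2 arrays overlapped between the times. Its vehicle arrays all lay lower at 3 h than at 24 h, so this difference reflects movement of vehicle. Against baseline the mean change of the BCL2 list was -0.09 in vehicle at 3 h and 0.003 in vehicle at 24 h, so vehicle movement enters there too. Interferon genes were called negative, 9 of 24 against 2, with OAS1 lowered more at 24 h (adjusted p = 0.3 with an estimated correlation), and immediate-early genes negative, 8 of 23 against 1 (adjusted p = 0.22 with an estimated correlation). Adjusted over the list alone, these pairs of counts were 8 and 2, 9 and 0, 9 and 2, and 9 and 1. The immediate-early call was lost without the dimmest 25% of genes (adjusted p = 0.054). Limma called 4100 genes in this test, 1973 with positive and 2127 with negative differences, and 2199 and 2011 with each array's level trend removed, which was chosen after seeing the data.

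Of the 122 genes that changed at least 1.5-fold in vehicle cells at 3 h against the baseline, 97 were higher. ARAP2 was higher by 2.23 ± 0.14, CYP1B1, a cytochrome P450 that oxidises estrogens, by 2.11 ± 0.04 and SLC7A11, a cystine transporter gene, by 1.59 ± 0.09. CREB5 (1.51 ± 0.10) and PHLDA2 (1.49 ± 0.09, 1 of 2 probe sets called) came next, and the baseline means of ARAP2 and CREB5 were dim. PCK1, a gluconeogenic enzyme gene, was lower (-1.41 ± 0.08), as were TSKU (-1.07 ± 0.05), CX3CR1 (-0.81 ± 0.10), STC2 (-0.79 ± 0.03) and NUDT6 (-0.77 ± 0.06). Limma's Benjamini-Hochberg adjusted p-values of these 10 ran from 1.1e-17 for CYP1B1 to 9.8e-06 for CX3CR1.

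Cholesterol genes were higher in vehicle at 3 h in 13 of 18 cases and lower in 0, also when adjusted over the list alone, by a median of 0.17 (camera on limma's fit, Benjamini-Hochberg adjusted p = 2.9e-11, and adjusted p = 0.025 with an estimated correlation). G1/S genes were higher in 18 of 42 cases and lower in 3 (19 and 3 adjusted over the list alone), with adjusted p = 0.33 with an estimated correlation. Ribosome biogenesis genes were higher in 12 of 27 and lower in 2, also adjusted over the list alone, again with adjusted p = 0.33 with an estimated correlation. Estrogen-induced genes were lower in 11 of 37 and higher in 4 (16 and 5 adjusted over the list alone), with a camera Benjamini-Hochberg adjusted p of 0.033 and adjusted p = 0.33 with an estimated correlation. That last call was lost without baseline array C (adjusted p = 0.087), vehicle 3 h array C (0.05) or vehicle 3 h array D (0.055). Limma called 2393 genes (20%) at the Benjamini-Hochberg threshold, 1190 higher and 1203 lower, with 97 and 25 of them changed at least 1.5-fold. Centring each array on its median gave 1067 higher and 1502 lower. Of those 97 genes, 75 were lower with E2 than with vehicle at 3 h, on shared vehicle arrays. The log2 difference between the 3' and 5' ACTB control probe sets was 0.466 ± 0.010 (SD, n = 4) at baseline and 0.315 ± 0.027 in vehicle at 3 h, which accompanies these groups of genes. For GAPDH it was -0.124 ± 0.014 at baseline and -0.116 ± 0.0085 in vehicle at 3 h (SD, n = 4), with overlap of arrays. Fitted to these 8 arrays alone, the real split called 3 lists. At least as many were called in 14 of the 35 splits, the real one counted.

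Vehicle cells at 24 h had higher levels of mitotic genes than the baseline, on arrays whose ACTB 3' to 5' differences also parted without overlap. The GAPDH differences of these arrays overlapped. Of 40 G2/M genes 33 were higher and 0 lower (38 and 1 adjusted over the list alone), by a median of 0.42, with a camera Benjamini-Hochberg adjusted p of 1.2e-46 and adjusted p = 0.0021 with an estimated correlation. RRM2, a ribonucleotide reductase subunit gene, was higher by 1.21 ± 0.06, HDC by 0.79 ± 0.04, the kinesin gene KIF15 by 0.79 ± 0.08, TMEM45A by 0.78 ± 0.08 and the dim AKR1D1 by 0.77 ± 0.09. CYP1A2, on a probe set that may cross-hybridise, was lower (-1.85 ± 0.05), and so were ATRNL1 (-1.04 ± 0.08), GREB1 (-1.0 ± 0.07, with 2 of 3 probe sets called), SPINK4 (-0.75 ± 0.05) and AKR1C2, which may also cross-hybridise (-0.72 ± 0.03). These 10 genes had limma Benjamini-Hochberg adjusted p-values between 6.2e-14 for CYP1A2 and 1.2e-05 for AKR1D1.

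Estrogen-repressed genes were higher in vehicle at 24 h in 7 of 17 cases and lower in 1, also adjusted over the list alone (adjusted p = 0.032 with an estimated correlation). Estrogen-induced genes were lower in 10 of 37 and higher in 5 (14 and 7 adjusted over the list alone), with adjusted p = 0.22 with an estimated correlation. Fatty acid synthesis genes were lower in 3 of 11 and higher in 0 (4 and 0 adjusted over the list alone), with adjusted p = 0.032 with an estimated correlation. Cholesterol genes were lower in 9 of 18 and higher in 1 (11 and 1 adjusted over the list alone), with adjusted p = 0.081 with an estimated correlation. Amino acid and unfolded protein response genes were lower in 6 of 26 and higher in 0 (9 and 0 adjusted over the list alone), with adjusted p = 0.27 with an estimated correlation. Limma called 1426 genes (11.9%) at the Benjamini-Hochberg threshold, 903 higher and 523 lower, of which 29 and 8 changed at least 1.5-fold. The split became 778 higher and 755 lower when each array was centred on its median and 853 and 708 after quantile normalization again, so the size of the excess depends on the scaling. The ACTB 3' to 5' difference was 0.397 ± 0.032 in vehicle at 24 h and 0.466 ± 0.010 at baseline (SD, n = 4), without overlap of arrays. For GAPDH it was -0.117 ± 0.032 in vehicle at 24 h and -0.124 ± 0.014 at baseline (SD, n = 4), with overlap. In 4 of the 35 splits of these 8 arrays, the real one counted, at least as many lists were called.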

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

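The tests of mixed vehicle RNA, of baseline shifts, of RNA quality and of shared or shifted vehicle arrays were chosen after the result was seen, while the trend test and the counts of other splits were fixed before their results were seen.

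Single arrays stood apart in 14 of the 298 sets of 4 arrays examined, against 14.9 by chance. The value given is the gap to the nearest array over the range of the group, with a critical value of 0.829. E2 24 h array D stood apart in its median level (0.88) and E2 3 h array D in the spread of its values (0.846). Single genes did so for ATP8A2 on vehicle 3 h array A (0.877), CACNA2D3 on E2 3 h array D (0.891), CLDN4 on E2 3 h array A (0.95) and CYP1A2 on baseline array A (0.931). EGR3 stood apart on E2 24 h array D (0.861) and on vehicle 24 h array D (0.932), GADD45B on E2 24 h array A (0.832) and GDF15 on E2 24 h array D (0.892). The others were HSD11B2 on vehicle 3 h array D (0.829), KIF15 on vehicle 24 h array D (0.903), OCLN on E2 3 h array B (0.942) and S100A7 on E2 24 h array B (0.978).

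The E2 effect differed between 24 h and 3 h for 78 of the 86 genes named in the E2 comparisons, by the interaction test in limma, 39 in each direction. Most of these genes were named for large or clear changes in the same data, so a high share is built in. Over all genes tested the share was 34.3%. Positive differences were found for MMP26 3.74, S100A7 3.40, DOCK10 2.81, ATRNL1 2.61, PDZK1 2.53, DLX2 2.22, RND3 1.93, AGR2 1.75, DHRS2 1.68, EGFL6 1.64, PDE4B 1.63, GATA3 1.56 and MET 1.55. They were also found for TGFBR2 1.55, RASL11B 1.5, RGS2 1.38, ARSJ 1.36, ACOX2 1.18, MCM10 1.13, MCM5 1.09, MCM6 1.04, TWIST1 1.00, NAV3 0.92, TFAP2A 0.89, ACAT2 0.85 and ELOVL2 0.84. Smaller ones were found for PPP1R3C 0.79, IDI1 0.77, ELOVL6 0.75, GREB1 0.71, PPFIBP2 0.70, ID2 0.69, EBP 0.64, CKS1B 0.47, TGIF1 0.41, CDK1 0.40, OCLN 0.36, PRC1 0.35 and ESR1 0.12. The ESR1 difference (limma adjusted p of 0.033) lost its call, at adjusted p from 0.057 to 0.072, without vehicle 3 h array A or C, E2 3 h array B or D, vehicle 24 h array B or C, or E2 24 h array C. Negative differences, from the smallest, were HSPB8 -0.15, EFNA1 -0.17, ERBB2 -0.17, BIK -0.33, ACACB -0.47, RET -0.47, IRF1 -0.48, WNT4 -0.54, CDH1 -0.58, FZD7 -0.58, PSMB9 -0.59, SIAH2 -0.60 and VEGFA -0.72. That of HSPB8 (limma adjusted p of 0.049) lost its call, at adjusted p from 0.055 to 0.12, without vehicle 3 h array A, B or C, E2 3 h array B, C or D, vehicle 24 h array A, B or D, or E2 24 h array B, C or D. Among other alternatives, limma also lost the HSPB8 call with the replicate letter as a block (adjusted p of 0.063). With only the compared groups in the fit it lost those of HSPB8 (0.069) and ESR1 (0.059). With the mean of all probe sets of a gene the RET difference was 0.13, and those of GREB1 (0.05, limma adjusted p of 0.72), ERBB2 (-0.12, 0.25) and ESR1 (0.12, 0.22) lost their calls. Larger ones were MICB -0.81, SLC2A1 -0.92, NDRG1 -0.98, BAMBI -1.04, PFKFB3 -1.13, ELF3 -1.17, SPRY4 -1.29, CNR1 -1.31, MYC -1.33, STON1 -1.36, BCAS1 -1.45, FOSL2 -1.45 and TGFA -1.59. The furthest below 0 were OAS1 -1.81, SMAD7 -1.82, RASGRP1 -1.99, KAZN -2.13, SLC14A1 -2.25, CX3CR1 -2.28, HDC -2.34, HSD11B2 -2.34, GADD45B -2.36, GDF15 -2.59, ATP8A2 -2.86, SERHL2 -2.97 and CACNA2D3 -3.03. Movement of vehicle between the times enters all of these differences, positive and negative. The vehicle arrays of CX3CR1, BAMBI and BIK, for example, all lay higher at 24 h than at 3 h, and those of ARSJ all lay lower. The 7 lists with a called difference had medians of 0.71 for G1/S, 0.42 for cholesterol, 0.22 for G2/M, 0.12 for luminal identity, -0.071 for immediate-early genes, -0.16 for interferon genes and -0.21 for the BCL2 family. With an estimated correlation 2 of the 7 were still called, G1/S and cholesterol, while the other 5 had adjusted p-values from 0.084 to 0.3.

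The D arrays of both E2 groups deviated from their groups together, with a correlation across genes of 0.370, where other pairs of arrays from different groups had a median of 0.00147 and at most 0.251. Removing each array's trend of signal with level left a correlation of 0.271, which argues against such a trend as the whole cause. Vehicle RNA mixed into both samples would shrink their changes, but the slopes on the other 3 E2 arrays were 0.977 at 3 h and 0.990 at 24 h. No biological explanation was tested, and a shared handling step of these 2 samples stays open.

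Genes changed at least 1.5-fold in vehicle at 3 h lay near the baseline again at 24 h, with a median ratio of the changes of 0.0403 over 122 genes (quartiles -0.0653 and 0.134). A shift of the baseline arrays would leave a ratio near 1, so the ratio argues against it. RNA quality of the vehicle 3 h arrays cannot be told apart, because 1 of 3 control transcripts moved in its 3' to 5' difference without overlap of arrays, ACTB (-0.151), while GAPDH moved by 0.00812. A passing response of the cells to the vehicle or to handling also stays open, as untested.

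Of 97 genes raised at least 1.5-fold in vehicle at 3 h, 75 were lower with E2 than with vehicle at 3 h (17.0 for independent lists) and 10 higher, with a median vehicle change of 0.73 and a median E2 change of -0.63. Both comparisons share the vehicle arrays, so 17.0 is not the count to be seen without an E2 effect. Over all genes the correlation was -0.246 and the covariance -0.0117, where 100 simulations of unchanged groups gave -0.500 and -0.00202. With different vehicle arrays on each side, the correlation stayed between -0.168 and -0.227 over the 6 splits, which argues against chance values of the shared arrays. Whether all transcripts shifted on the vehicle 3 h arrays alone was not decided. The cholesterol list kept a median of 0.15 in E2 at 3 h against baseline, with 15 of 18 genes above it. Its medians of 0.17 in vehicle and -0.017 for E2 against vehicle already implied this. The rise of those 18 genes was thus not on the vehicle arrays alone, but they cannot speak for all transcripts. A shift of the 97 genes on the vehicle 3 h arrays alone cannot be told apart from an opposing E2 effect, because both give a low share of the vehicle change in E2 cells (median 0.214).

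For the counts of genes called, the real split exceeded every other split of the same arrays. Other splits mix the compared groups, so a real difference widens their spread and few calls there are built in. The smallest share that the splits of 2 groups can give is 1 of 35. Such splits cannot part treatment from handling shared by a group. Fitted to the compared groups alone, the real split called 3368 genes for E2 at 3 h (highest other 0), 5018 for E2 at 24 h (0), 2411 for vehicle at 3 h (1) and 1378 for vehicle at 24 h (0), and was the 1 split of 35 with as many in each. For the difference between times it called 3901 genes against at most 1183, 1 of 100 splits drawn. For the counts of lists called by camera, chance cannot be excluded, and the splits do not measure it alone. Some of the other splits hold the compared groups unequally, so part of a real difference can enter their list calls. Counting the real split, at least as many lists came in 3 of 35 splits for E2 at 3 h (real 4, highest other 4), 6 of 35 for E2 at 24 h (5 and 6), 14 of 35 for vehicle at 3 h (3 and 4) and 4 of 35 for vehicle at 24 h (6 and 9). For the difference it was 4 of 100 (7 and 8). The draws for the difference, of genes as of lists, shuffled arrays over all E2 and vehicle groups. Effects of E2 and of time therefore enter them, and they cannot decide whether the difference arose by chance.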

How the results depend on the processing

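The alternatives with the E2 D arrays left out together and with each array's level trend removed were chosen after seeing the data, and all others beforehand. All 136 gene results named in the comparisons kept their direction and their side of the 0.05 threshold in 2610 values under the alternative fits, and their side at a threshold of 0.01. Requiring at least a 1.5-fold change ended 12 of their calls, for ESR1, TFF1 and FGFR1 at both times, CDH1, CDK1, CKS1B and IRF1 with E2 at 24 h, and NQO1 and HMOX1 in vehicle at 24 h. For the 66 differences between the times that are given only among the values that differ, 1685 of 1715 values kept both, and 29 lost the call. With the mean of all probe sets of a gene RET reversed from -0.47 to 0.13, GREB1 became 0.05 and ERBB2 became -0.12, no longer called, and the cause was not tested. The other calls lost were of HSPB8 (adjusted p up to 0.15 by limma) and ESR1 (up to 0.22). Of these differences 16 fell short of 1.5-fold, and HSPB8, ESR1 and ERBB2 failed at 0.01. Requiring at least a 1.5-fold change reduced the genes called to 635 for E2 at 3 h, 759 for E2 at 24 h, 767 for their difference, 122 for vehicle at 3 h and 37 for vehicle at 24 h. A threshold of 0.01 left 1573 genes for vehicle at 3 h and 784 for vehicle at 24 h. Stricter thresholds call fewer genes by construction. With single arrays left out in turn, the calls ranged from 3444 to 3709, 5008 to 5458, 3897 to 4299, 1979 to 2200 and 1111 to 1267 in that order, and the lists from 4 to 5, 5 to 7, 7 to 9, 3 to 5 and 6 to 7. Camera with an estimated correlation called 1 list for E2 at 3 h, 2 for the difference, 1 for vehicle at 3 h and 3 for vehicle at 24 h. Fry, which does not set a list against other genes, called 15, 17, 16 and 11 lists for E2 at 3 h, E2 at 24 h, the difference and vehicle at 3 h. Without both E2 D arrays 3770, 5151 and 4103 genes were called for the E2 comparisons and their difference. Removing level trends gave 3877, 5409, 4210, 2494 and 1542. The overlap of the 2 times ranged from 1959 to 2144 genes around 2069. Dim signals limit genes near background, such as PGR.

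With the replicate letter as a block, 3665, 5479, 4078, 2332 and 1410 genes and 4, 5, 7, 4 and 7 lists were called, and 2037 genes overlapped. The HSPB8 difference between the times lost its call there (limma adjusted p of 0.063). The letters did not pair the arrays of E2 with vehicle or of vehicle with baseline, where 0 of 4 pairs in each comparison had deviations correlated above 0.1. Pairs between E2 at 3 h and E2 at 24 h were not in that count, and their D arrays were correlated at 0.370. Over all groups the best matching array carried the same letter in 18 of 80 cases.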

Other observations

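The gene lists on p53, the aryl hydrocarbon receptor, NRF2 and TGF-beta, and the tests on them, were chosen only after the result was seen.

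TGFA, a ligand of the epidermal growth factor receptor, rose by 1.67 ± 0.04 at 3 h, the receptor gene MET rose by 1.24 ± 0.04 at 24 h, and ERBB2 fell by 0.97 ± 0.04 at 24 h. Of 29 receptor tyrosine kinase and growth factor genes, 7 rose and 10 fell at 3 h, and 11 rose and 13 fell at 24 h. PMAIP1, a pro-apoptotic gene of the BCL2 family, rose by 1.94 ± 0.07 at both times. Of 11 fatty acid synthesis genes 7 rose and 2 fell at 24 h, with ELOVL6 up by 1.06 ± 0.04 and ACACB down (-1.01 ± 0.04).

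Luminal genes moved in different directions. At 3 h TFAP2A fell by 0.97 ± 0.04 and ELF3 rose by 1.15 ± 0.04, and at 24 h AGR2 rose by 1.60 ± 0.03. FZD7 was still raised at 24 h, by 1.40 ± 0.04. Besides OAS1, which fell by 0.62 ± 0.05 at 3 h, the interferon-related genes IRF1 (-0.58 ± 0.04) and PSMB9 (-0.60 ± 0.05) were lower at 24 h.

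Among the lists not called at 3 h, G1/S genes had 12 of 42 higher and 6 lower, G2/M genes 14 of 40 and 5, and cholesterol genes 3 of 18 and 7. Ribosome biogenesis genes had 0 of 27 higher and 8 lower, coregulators 3 of 11 and 5, quiescence genes 4 of 18 and 7, amino acid and unfolded protein response genes 8 of 26 and 7, and basal markers 3 of 8 and 1.

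As a hypothesis, TGF-beta and BMP pathway genes as a group may be lowered by estradiol at 3 h. Of 21 measured, 11 fell and 2 rose, including TGFBR2 (-2.00 ± 0.06), ID2 (-1.50 ± 0.04) and TGIF1 (-1.18 ± 0.03), named after their values were seen. Without the members whose values had prompted the list, 7 of 16 fell and 1 rose. On these, camera's Benjamini-Hochberg adjusted p with an estimated correlation was 0.018, and at 24 h it was 0.15. The full list was also higher in vehicle at 3 h than at baseline (0.045, and 0.15 without the prompting members), on the vehicle arrays that the E2 comparison at 3 h uses, so a shift of those arrays stays open. The 3' to 5' differences of ACTB (0.385 ± 0.032 with E2, 0.315 ± 0.027 with vehicle, SD, n = 4) and GAPDH (-0.138 ± 0.011 and -0.116 ± 0.0085) also parted these arrays at 3 h without overlap. The same genes include both activators and inhibitors of the pathway, so a direction of signalling does not follow.

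A second hypothesis is that NRF2 targets are lower in vehicle at 24 h than at baseline, where 8 of 16 fell and 0 rose, with NQO1 at -0.39 ± 0.03 and HMOX1 at -0.25 ± 0.05, both named after their values were seen. Without the members that prompted the list, among them AKR1C genes whose probe sets may cross-hybridise, 4 of 11 fell and 0 rose, and the adjusted p with an estimated correlation was 0.015. The ACTB 3' to 5' difference also moved without overlap between these arrays, from 0.466 ± 0.010 at baseline to 0.397 ± 0.032 in vehicle at 24 h (SD, n = 4). That of GAPDH overlapped between them. The list also passed as higher in vehicle at 3 h (0.015), where TXNRD1 stood at 0.70 ± 0.03 and HMOX1 at 0.67 ± 0.05, also named after their values were seen, beside the ACTB difference in those arrays. With E2 10 of 16 were lower at 3 h (0.016, and 0.091 without the prompting members), against these same vehicle arrays, and 10 of 16 at 24 h (0.044, and 0.41 without).

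The other hypotheses did not pass their tests. P53 targets as a list were not shown to be higher at 3 h, although MDM2 rose by 1.87 ± 0.06 (named after its value was seen) beside GDF15 and PMAIP1. Without the prompting members 2 of 17 rose and 7 fell, with an adjusted p of 0.41 with an estimated correlation and a median of -0.02. Aryl hydrocarbon receptor targets, tested because CYP1B1 was higher in vehicle at 3 h, had an adjusted p of 0.067 with an estimated correlation without CYP1B1 and CYP1A2, so this stays undecided. Over the 4 lists in all 5 comparisons, 9 of 20 tests passed with full lists and 3 of 20 without the prompting members, with NQO1 in 2 lists. Other splits of the arrays were not counted for these lists.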
